A study of Geissois pruinosa and Geissois racemosa with 6 samples.

How the data were processed

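Leaves of 6 wild plants, 3 of Geissois pruinosa and 3 of Geissois racemosa, were frozen in liquid nitrogen, and polyadenylated RNA was sequenced as paired-end reads from stranded Illumina libraries, per the labels' protocols. Per the labels, each library came from one plant. According to the series' design text, the authors assembled the reads of one plant per species de novo and used the G. pruinosa transcriptome as the reference for both species. Which plant was assembled, the assembler, the read mapper, the counting program, its use of strand and its treatment of reads that match several contigs are not given in the sources used here. The deposited values are raw read counts per contig, one file per library, with the same 54969 G. pruinosa contigs in each; per the file headers the columns hold counts, and the values were whole numbers with totals that differed between libraries. The files hold no gene names, lengths or sequences of the contigs. The lists of gene families drawn up beforehand were therefore not tested, and contigs are named by their numbers.

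This processing affects the measurements in known ways. Reads of G. racemosa can be counted only where they match a G. pruinosa contig, so a low count in G. racemosa can come from a low level or from sequence that differs. A de novo assembly can hold alleles, fragments or close copies of one gene as separate contigs, and how their shared reads were divided is not known, so a single contig does not stand for a gene.

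Libraries were grouped by the species prefix and number in their titles. Totals ran from 23661301 to 64908952 counts. No library held the same values as another. The main test compared G. pruinosa with G. racemosa in edgeR 4.0.16 (R 4.3.3) on the counts as deposited, with TMM scaling (factors from 0.902 to 1.11), contigs kept by filterByExpr with its default minimum count of 10, and glmQLFit and glmQLFTest with species as the only term. P-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was called. Log2 fold changes are G. pruinosa minus G. racemosa. Their standard error was taken as the absolute log2 fold change divided by the square root of the F statistic. Abundance classes without pruinosa plant 3 use the mean of the species means, so that 2 plants weigh as much as 3. CPM values use the TMM-scaled totals, except for ratios between libraries, which use plain totals. Correlations used log2 CPM with a prior count of 2. The biological coefficient of variation was the square root of the common dispersion fitted within each species. Differences between species in single values per library were tested by exact two-sided permutation of the 6 libraries, for which the smallest p is 0.1. Limits from a count of 0 use 3 counts and cover counting error only, and the reads carry no molecular identifiers that would make them independent molecules.

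The contigs named in the text follow a rule set before the data were examined: among contigs called with at least a 2-fold change, no overlap between species and at least 10 counts in each library, the contig with the largest change in each direction and the most abundant of the others. The grouping, the main test and the alternatives were also fixed then. The latter were RLE, upper-quartile and no scaling, TMM factors from contigs with at least 10 counts in all libraries, no filter and a strict filter on low counts, DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, other count minimums, thinning to the smallest total, and leaving out each library. Fits without both pruinosa plant 3 and racemosa plant 1, with part of racemosa plant 1 subtracted from pruinosa plant 3, on thinned libraries, and without pruinosa plant 3 under other filters, scalings and tools were added after seeing the data.

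The replicate numbers name different plants at different sites, and nothing in the labels pairs them across species, so the main fit has no block. The count test was tested on simulated data for 43447 contigs with the means, totals and dispersions of these libraries and 200 changed contigs. It recovered 0 of 50 contigs changed 2-fold, 1 of 50 changed 4-fold, 12 of 50 changed 8-fold and 30 of 50 changed 32-fold, with 3 false calls. In this simulation, most contigs changed 8-fold or less were thus missed. The share recovered depends on how many contigs differ and on the spread, which here includes pruinosa plant 3. The simulated shares therefore do not give the share of real differences that was missed.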

Results

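Leaf messenger RNA was sequenced from 6 wild plants of the genus Geissois (Cunoniaceae), woody plants of New Caledonia. Of these plants, 3 belonged to Geissois pruinosa, which the labels describe as a nickel hyperaccumulator, a plant that concentrates nickel in its leaves to exceptional levels. The other 3 belonged to Geissois racemosa, described as a species that does not accumulate nickel. Each plant grew at its own site. The G. pruinosa leaves were collected on 11 March, and the G. racemosa leaves on 11 June (plant 1) and 12 June (plants 2 and 3) of the same year. The reads of both species were counted on the same 54969 contigs, the assembled transcript sequences of G. pruinosa. The contigs carry numbers only, and gene names were not available for them here, so contigs are described by their abundance and by the species and plants in which they were found.

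The total count per library was 51545408 ± 3634546 in G. pruinosa and 46179690 ± 20883254 in G. racemosa (mean ± SD, n = 3 plants each). The exact permutation test gave p = 0.8 for this difference (two-sided, 3 against 3 plants). The range ran from 23661301 in racemosa plant 1 to 64908952 in racemosa plant 2. A count of 3, the upper limit that a count of 0 allows, corresponded to between 0.0462 CPM (counts per 1000000 counts of the library) in racemosa plant 2 and 0.127 CPM in racemosa plant 1. The 10 highest contigs held 8.74% ± 1.71 of the counts in G. pruinosa and 9.003% ± 1.68 in G. racemosa (SD, n = 3 plants each, exact two-sided permutation p = 0.7). The 100 highest held 25.6% ± 4.93 and 22.4% ± 2.96 (SD, n = 3 plants each, exact two-sided permutation p = 0.5). The smallest p that such a test can give with 3 against 3 plants is 0.1, so it cannot pass 0.05.

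The first question was how much of the G. pruinosa contig set was detected in each species. More contigs had at least 10 counts in every G. pruinosa library than in any G. racemosa library. At least 10 counts were found for 44886 ± 5456 contigs in G. pruinosa and 37478 ± 5275 in G. racemosa (SD, n = 3 plants each). The exact two-sided permutation test of this difference gave p = 0.1, the smallest value that 3 against 3 plants can give. After every library was thinned to the total of racemosa plant 1, the means were 36166 ± 2697 and 32322 ± 1583 contigs, with an exact permutation p = 0.1 (n = 3 plants each). The difference of 7408 contigs was 4266 without pruinosa plant 2 and 4372 without racemosa plant 1 (exact permutation p = 0.4 for each). At a minimum of 50 counts the species overlapped, with 25608 contigs in pruinosa plant 1 and 26326 in racemosa plant 2. The contigs with 0 counts numbered 3481 in pruinosa plant 1, 2 in pruinosa plant 2 and 3134 in pruinosa plant 3. They numbered 8727, 5011 and 4162 in racemosa plants 1, 2 and 3. Pruinosa plant 2 thus differed from the other plants of its species by more than these differed from racemosa plant 3.

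**Figure D1:**
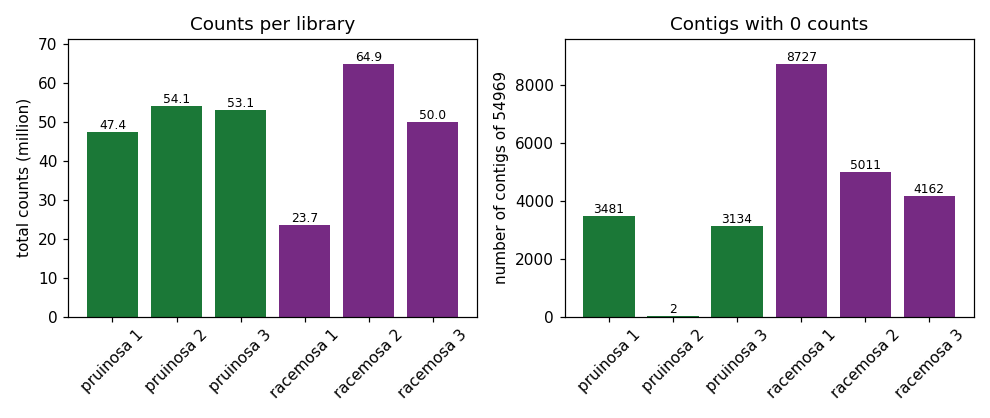
Total counts (left) and the number of contigs with 0 counts (right) for each of the 6 libraries, as bars from 0, with G. pruinosa in green and G. racemosa in purple. Racemosa 1 had the lowest total, 23661301 counts, and pruinosa 2 had 2 undetected contigs against 3134 to 8727 in the other libraries.

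The next count concerned contigs found in G. pruinosa only. At least 10 counts in each of the 3 G. pruinosa libraries and 0 in each of the 3 G. racemosa libraries were found for 222 contigs. The opposite pattern could not be assessed with all libraries, because pruinosa plant 2 had only 2 contigs with 0 counts. Without this plant, 228 contigs were found in G. pruinosa only and 1 in G. racemosa only. These counts do not compare the species, because pruinosa plant 3 could also hardly have 0 counts where racemosa plant 1 was well counted. Over the 8311 contigs with at least 500 counts in racemosa plant 1, the lowest CPM ratio of pruinosa plant 3 to that library was 0.294. With all libraries and a minimum of 50 counts, the number of contigs found in G. pruinosa only was 52. With up to 2 counts allowed in each library of the other species it was 509. A further count without any minimum gave 2379 contigs with 0 counts in all G. racemosa libraries and at least 1 count in G. pruinosa. The contigs were assembled from G. pruinosa reads, so transcripts present only in G. racemosa could not be counted. Without pruinosa plant 3 the number of contigs found in G. pruinosa only was 480, without pruinosa plant 1 it was 392, and without racemosa plant 3 it was 394.

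The second question was how similar the plants of one species were to each other. The G. racemosa plants resembled each other more closely than the G. pruinosa plants did. Spearman's rho between log2 CPM values, across contigs, lay between 0.91 and 0.93 for the 3 pairs of G. racemosa libraries and between 0.85 and 0.89 for the 3 pairs of G. pruinosa libraries. Between the species it lay between 0.79 and 0.90 over 9 pairs. Contigs are not independent replicates, so these values describe the libraries only. The biological coefficient of variation, the between-plant spread that edgeR estimates beyond counting error, was 0.597 in G. pruinosa and 0.508 in G. racemosa.

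By Spearman's rho, pruinosa plant 3 was closer to racemosa plant 1 (0.904) than to pruinosa plant 1 (0.849) or pruinosa plant 2 (0.891). By Pearson's r of the same values it was as close to pruinosa plant 2 (0.9104) as to racemosa plant 1 (0.9103). On the first principal component of the log2 CPM values (46.3% of the variance), it lay at -41.7, nearer to pruinosa plant 2 (-139.9) than to racemosa plant 1 (156.7). On the second (21.4%), pruinosa plant 3 lay at -145.6, nearer to racemosa plant 1 (-79.6) than to pruinosa plant 2 (-38.1) or plant 1 (92.7). The counts of pruinosa plant 3 had a lower limit relative to racemosa plant 1 at contigs well counted there. Over the 8311 contigs with at least 500 counts in racemosa plant 1, the lowest ratio of the CPM in pruinosa plant 3 to that in racemosa plant 1 was 0.294. Ratios below this value were found for 1028 of these contigs in pruinosa plant 1, 642 in pruinosa plant 2, 220 in racemosa plant 2 and 136 in racemosa plant 3. This feature of the library of pruinosa plant 3 is given beside the comparison of the species below, and the comparison was also made without it.

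**Figure D2:**
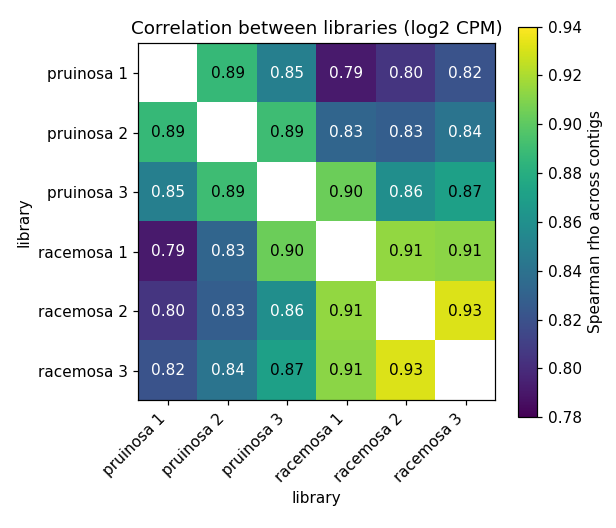
Spearman's rho between log2 CPM values across 43447 contigs for each pair of the 6 libraries, on a colour scale from 0.78 to 0.94. The pair of pruinosa 3 and racemosa 1 reached 0.90, and the pairs within G. racemosa 0.91 to 0.93.

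**Figure D3:**
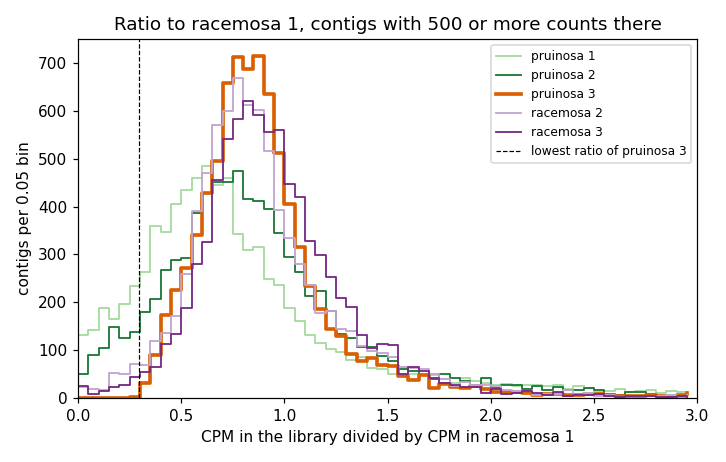
Number of contigs (y axis, bins of width 0.05) by the ratio of the CPM in a library to the CPM in racemosa 1 (x axis), for the 8311 contigs with at least 500 counts in racemosa 1. The line of pruinosa 3 begins at its lowest ratio of 0.294 (dashed line), while the other 4 libraries have contigs below it. Ratios above the axis limit are not drawn.

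The main question was which contigs differed in abundance between the nickel hyperaccumulator and the species that does not accumulate nickel. Of 43447 contigs tested, 492 (1.13%) differed between the species at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, n = 3 plants per species). Of these, 483 were higher in G. pruinosa and 9 were lower. All 492 differed at least 2-fold, and in all of them the 3 libraries of one species lay above the 3 of the other. Over all tested contigs, the species did not overlap in 25.6% (6392 higher and 4740 lower in G. pruinosa), where chance gives 10%.

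The 483 contigs higher in G. pruinosa had a median log2 fold change of 6.01. With the 100 of them that had 0 counts in all G. racemosa libraries set to their lower bound (3 counts over the G. racemosa libraries together), the median was 5.56. Their median level was 4.17 CPM in G. pruinosa and 0.0517 CPM in G. racemosa. In 391 of the 483 the mean in G. racemosa was under 1 CPM, and in 126 every one of the 6 libraries had at least 10 counts. The 9 contigs lower in G. pruinosa were well counted in both species, with medians of 21.3 CPM in G. pruinosa and 84.3 CPM in G. racemosa and log2 fold changes from -2.69 to -1.77. By abundance, 145 higher and 0 lower contigs had a mean under 1 CPM over the 6 libraries, 229 and 2 had 1 to 10 CPM, 99 and 5 had 10 to 100 CPM, and 10 and 2 had 100 CPM or more.

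**Figure D4:**
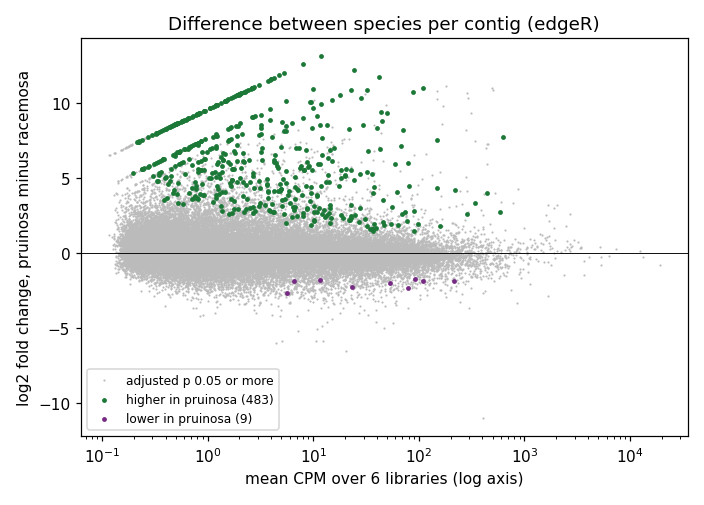
Log2 fold change between the species (y axis, G. pruinosa minus G. racemosa) against the mean CPM over the 6 libraries (x axis, log scale) for the 43447 tested contigs. The 483 contigs called higher in G. pruinosa are green and the 9 called lower are purple, and the highest straight line of green points holds contigs with 0 counts in all G. racemosa libraries, whose fitted fold change is no measured ratio.

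Among the called contigs with at least 10 counts in every library, Gpru_v1_contig_177 had the largest increase in G. pruinosa. It stood at 1246 ± 1452 CPM in G. pruinosa and 5.75 ± 5.58 CPM in G. racemosa (SD, n = 3 plants each), a log2 fold change of 7.77 with a standard error of 1.34 and an edgeR adjusted p of 0.0481. Its level varied widely within G. pruinosa, from 208 CPM in plant 3 to 2906 CPM in plant 2, so the SD exceeded the mean. Of the other contigs counted this way and called higher in G. pruinosa, Gpru_v1_contig_1686 was the most abundant over the 6 libraries. It had 1026 ± 305 CPM in G. pruinosa and 155 ± 43.5 CPM in G. racemosa (SD, n = 3 plants each), a log2 fold change of 2.73 with a standard error of 0.38 (edgeR adjusted p = 0.0314).

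Among the 9 contigs called lower in G. pruinosa, Gpru_v1_contig_17352 had the largest decrease. It had 1.53 ± 0.301 CPM in G. pruinosa against 9.87 ± 3.89 CPM in G. racemosa (SD, n = 3 plants each). Its log2 fold change was -2.69 with a standard error of 0.44 (edgeR adjusted p = 0.0442). The most abundant of the other contigs called lower in G. pruinosa, Gpru_v1_contig_2104, had 91.3 ± 17.0 CPM in G. pruinosa and 342.6 ± 95.3 CPM in G. racemosa (SD, n = 3 plants each). Its log2 fold change was -1.91 with a standard error of 0.32 (edgeR adjusted p = 0.0468). All 4 contigs kept their direction in each of the 22 alternative fits, and each lost its call in some of them: they remained past the threshold in 13, 15, 13 and 12 of the 22 fits, in the order given here. Of the 6 fits that left out one library, 1, 2, 1 and 1 kept the call. All 4 contigs lost it in the fit on contigs with at least 10 counts in all libraries (edgeR adjusted p from 0.0662 to 0.0920). They also lost it with the replicate number as a block (edgeR adjusted p from 0.133 to 0.178).

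**Figure D5:**
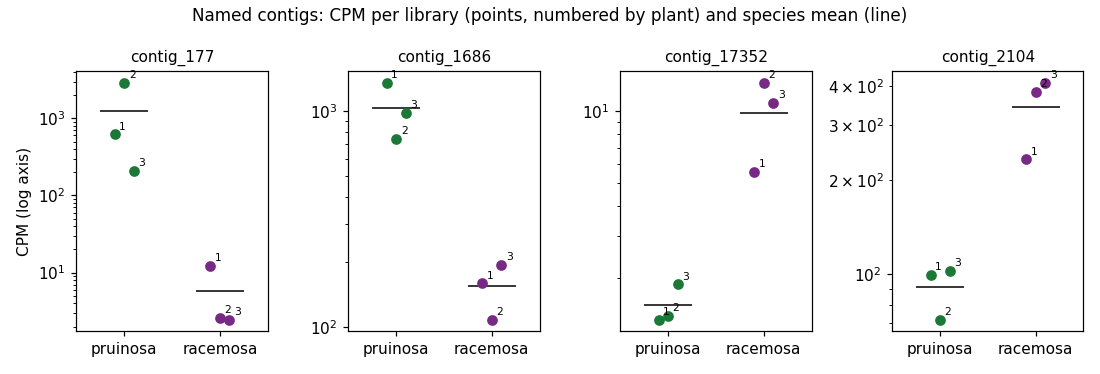
CPM (log axis, one scale per panel) of the 4 named contigs in each plant of G. pruinosa (green) and G. racemosa (purple), with the plant numbers beside the points and the species mean as a line. The libraries of the species do not overlap in any panel, and contig_177 spans 208 to 2906 CPM within G. pruinosa.

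The number of contigs that differed depended on single libraries. Without pruinosa plant 3, whose library did not fall below 0.294 of racemosa plant 1 at the 8311 contigs above, 2121 contigs differed, of which 1326 were higher in G. pruinosa and 795 were lower (edgeR, 2 against 3 plants). Of the 483 and 9 contigs called with all libraries, 481 and 9 were called again in the same direction. The median log2 fold change without this plant was 4.90 for the higher contigs (4.67 with the 240 that had 0 counts in all G. racemosa libraries at their lower bound) and -2.66 for the lower ones. The split by direction differed between abundance classes, taken from the mean of the species means. Contigs under 1 CPM were called higher in 438 cases and lower in 12, those with 1 to 10 CPM in 574 and 272, those with 10 to 100 CPM in 277 and 429, and those with 100 CPM or more in 37 and 82. At 10 CPM or more, 38.1% of calls were thus higher in G. pruinosa, and between 36.1% and 51.1% under 4 other scalings, so that with TMM factors from well counted contigs the higher calls were the more frequent there (428 and 410).

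Without pruinosa plant 2 the count was 41, and without racemosa plants 1, 2 or 3 it was 7, 0 and 2 (edgeR), against 4512 with DESeq2 on all 6 libraries. Contigs at an unadjusted edgeR p under 0.05 numbered 5819, 7707, 5907 and 7426 in these fits, in that order, against 7908 with all 6 libraries. They thus fell far less than the calls did, and each of these fits had a plant fewer. Species, site, habitat (serpentine maquis or rainforest on limestone in the labels) and month of collection changed together, so the comparison does not separate them.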

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

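With all 6 libraries, the count of 492 contigs (483 higher, 9 lower in G. pruinosa) moved by less than 1.5 times under 4 other scalings (420 to 580 contigs), limma-voom (398) and no filter on low counts (356, with 0 lower). It was 26 higher and 0 lower on contigs with at least 10 counts in all libraries, where fewer contigs were tested (28198), and 4512 with DESeq2 (3234 higher and 1278 lower, 4468 of them at least 2-fold); for DESeq2 the cause was not tested. With the replicate number as a block (replicate block) it was 16 higher and 0 lower. Same-numbered libraries had deviations from their species means correlated at -0.25, 0.05 and -0.23, and pruinosa 3 correlated best with racemosa 1 (0.34). The deviations within a species depend on each other, because they are taken from a mean of the same libraries. These correlations thus cannot decide whether the numbers pair the plants, and nothing in the labels pairs them. Leaving out one library gave from 0 to 2121 contigs, from 0 to 1326 higher and from 0 to 795 lower. The counts were 367 without pruinosa 1, 41 without pruinosa 2, 2121 without pruinosa 3, 7 without racemosa 1, 0 without racemosa 2 and 2 without racemosa 3. Contigs at an unadjusted edgeR p under 0.05 numbered 7248, 5819, 11076, 7707, 5907 and 7426 in the same order, against 7908 with all 6 libraries. The fits below were added after seeing the data. With all 6 libraries thinned to the smallest total, the count was 437 (427 higher, 10 lower). Without pruinosa 3, there were 2185 contigs on thinned libraries (1377 higher, 808 lower), 1537 among contigs with at least 10 counts in each other library (801 and 736), 7068 with DESeq2 (3708 and 3360, 6949 at least 2-fold) and 3103 with limma-voom (1916 and 1187, 3101 at least 2-fold). Subtracting part of racemosa 1 from pruinosa 3 gave 1641 (1112 and 529). Without both pruinosa 3 and racemosa 1 (2 against 2 plants) the count was 0, with 9792 contigs at an unadjusted edgeR p under 0.05. Contigs found in G. pruinosa only numbered 222, and 350, 127 and 52 with minimums of 5, 20 and 50 counts, 509 with up to 2 counts in the other species, and from 228 to 480 without one library. The coefficient of variation in G. pruinosa was 0.499 on contigs with at least 10 counts in all libraries and from 0.540 to 0.670 without one plant, and in G. racemosa 0.390 and from 0.461 to 0.522. The difference in the share of counts held by the highest contigs, -0.26 percentage points for the top 10 (G. pruinosa minus G. racemosa), was 2.49 for the top 50, 3.15 for the top 100 and 1.49 for the top 1000; with 3 against 3 plants the exact test cannot pass 0.05. The difference of 7408 detected contigs kept its sign in 10 alternatives, but was 2978 at a minimum of 50 counts (exact permutation p = 0.3), 4266 without pruinosa 2 and 4372 without racemosa 1 (exact permutation p = 0.4 each). The 4 named contigs kept theirs in 22 fits each, with edgeR adjusted p up to 0.229. Depth limited racemosa 1 most, where 3 counts are 0.127 CPM. The lists of gene families were not run, because the files pair no contig with a gene.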

Other observations

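The fits that leave out one library and the DESeq2 fit on all 6 were chosen before the data were examined, but what the fit without pruinosa plant 3 should show was written after its result. What the tests of the depth of pruinosa plant 2 and of racemosa plant 1 should show was written before their values were seen, the latter for a fit added after seeing the data; the other tests in this part were chosen after the results they concern had been seen.

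Some contigs were missing from a single plant. In pruinosa plant 1, 144 contigs had 0 counts while each of the other 5 libraries had at least 20. The same pattern was found for 73 contigs in racemosa plant 1, 12 in racemosa plant 2, 15 in racemosa plant 3 and 0 in pruinosa plants 2 and 3. After thinning to the smallest total the numbers were 88 in pruinosa plant 1, and 16, 15 and 16 in racemosa plants 1, 2 and 3. Thinning also lowers the number of contigs with at least 20 counts in the other libraries, so the fall in pruinosa plant 1 need not come from its own depth. After thinning, its number stayed above those of the G. racemosa plants, which were close to each other. Pruinosa plants 2 and 3 could hardly show this pattern. Plant 2 had only 2 contigs with 0 counts, and plant 3 had the lower limit relative to racemosa plant 1 given above. Because of that limit, counts in plant 3 at contigs well counted in racemosa plant 1 do not show that plant 1 alone lacked them. The number in pruinosa plant 1 may therefore be too high. Conversely, 522 contigs had at least 10 counts in pruinosa plant 2 and 0 in the other 5 libraries.

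Over the 12307 contigs with at least 10 CPM in racemosa plant 1, the 0.1% quantile of the CPM ratio of pruinosa plant 3 to racemosa plant 1 was 0.307. Among the other 29 ordered pairs of libraries the highest was 0.0467, between 2 G. pruinosa plants. A mixture made from 2 other libraries with a share set to 0.3 gave 0.288. This checks that the quantile returns a known share, and does not show that a mixture is present here. Pairs of plants of one species thus reached at most 0.0467, below 0.307. The labels do not say which plants shared a leaf state, so this value cannot exclude a shared leaf state of pruinosa plant 3 and racemosa plant 1. A hybrid without racemosa plant 1 as a parent would not be bounded by it more closely than racemosa plants 2 and 3, for which the quantile was at most 0.00384; a hybrid offspring of racemosa plant 1 was not tested. A label swapped with a G. racemosa plant is argued against by 381 contigs at least 8-fold higher in pruinosa plants 1 and 2 than in racemosa plants 2 and 3, where pruinosa plant 3 lay at a median of 0.806 of the way from G. racemosa to G. pruinosa on the log scale, while at 170 contigs at least 8-fold higher in racemosa plants 2 and 3 it lay at 0.307, nearer to G. racemosa. A candidate explanation is that reads or RNA of racemosa plant 1 entered this library, at about 29.4% of its counts by the lowest ratio over the 8311 contigs with at least 500 counts; whether the mixing was of RNA, libraries or reads stays open.

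Pruinosa plant 2 left 2 contigs undetected. Depth was not the reason, since after thinning to the smallest total it left 61 undetected and the next lowest library left 4515, and racemosa plant 2 had more counts. Contigs assembled from the reads of one plant should draw counts in the library of that plant. Pruinosa plants 1 and 3 had 0 counts at 3481 and 3134 contigs, which argues against either as the assembled plant. Among the G. pruinosa plants sequenced here this leaves plant 2, but whether its reads made the contigs was not shown directly. The 522 contigs counted in the library of plant 2 alone add nothing to this, because with 2 undetected contigs there no other library could hold such contigs in number. The labels do not name the assembled plant.

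Calls lay mostly on the side of G. pruinosa (483 of 492). Without pruinosa plant 3, lower calls rose from 9 to 795 and higher calls from 483 to 1326, so that 62.5% of calls were higher in G. pruinosa (95% exact binomial interval 60.4 to 64.6), while without pruinosa plant 1 or 2 all calls were higher. The scarcity of lower calls went with this library in edgeR but also with the tool, since DESeq2 called 1278 lower contigs on all 6 libraries. Without both pruinosa plant 3 and racemosa plant 1 (2 against 2 plants) edgeR made 0 calls, with 9792 contigs at an unadjusted p under 0.05. With 0 calls in either direction, that fit cannot show why lower calls were scarce. The low depth of racemosa plant 1 is not the whole reason for the excess that remained, since on thinned libraries without pruinosa plant 3 the share was 63.0% (60.96 to 65.05, with both intervals too narrow because contigs are not independent), but unthinned it was 52.1% among contigs with at least 10 counts in each other library, a filter that itself removes contigs near 0 in one species, 52.5% with DESeq2 and 38.1% at 10 CPM or more (36.1% to 51.1% under other scalings). Loss of G. racemosa reads at contigs whose sequence differs, and a difference between the species or their sites, may each account for the excess where it was found, and were not tested because the files hold no sequences.

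The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The split by species gave 492 contigs and the highest other split gave 0, so 1 of the 10 splits reached the real count, both for all contigs and for those differing at least 2-fold.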
